A study of Mus musculus with 4 samples.

How the data were processed

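RNA from 4 pools of 16 embryonic day 15 kidneys, 2 pools per maternal diet, was measured on Affymetrix Mouse Genome arrays after biotin labelling, per the labels' protocols. The deposited values are intensity values, 1 per probe set and array. They lie on a linear scale, from 0 to 13763, and each array was scaled so that its mean after trimming 2% of probe sets at each end is 250.0. The submitters' processing notes name RMA, but these deposited intensities are neither logarithmic nor brought to a shared distribution, as RMA output would be, so which software made them is not given in the sources used here. No genome build is named, and no coordinates are given. Groups and pool numbers were taken from the labels, and 0 columns were left unused.

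The intensities were turned to log2 after zeros, of which the arrays held 3, 1, 1 and 1, were set to 0.1. Control probe sets (64) were left out, as were the lowest 40% of the other 45037 by mean, which set a limit at a signal of 17.3. Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with default moderation, two-sided, with diet as the only term and Benjamini-Hochberg adjustment over 27022 probe sets. The fit has 2 residual degrees of freedom and a prior of 3.49. Errors printed after ± are standard errors of a log2 difference, iron-deficient minus control. Of the 45037 probe sets, 34945 have 1 gene symbol in the platform annotation, 932 several and 9160 none. Updating symbols through a table of the GRCm38.p6 assembly changed 0 of them, and no gene was named from a probe set with several.

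Gene lists were fixed before the data were examined, 41 in all, and the 37 with at least 5 tested members were compared with the other genes by camera with a preset correlation of 0.01, on the probe set with the highest mean of each gene. Ranges of a list's adjusted p cover this test over the alternative settings. A list's median is the median log2 difference of its members. Adjustment over the list alone was made within each list. The statistic with an estimated correlation rests on few degrees of freedom. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes.

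The text names, by a rule fixed before the data were examined, the 12 largest differences in each direction past an adjusted p of 0.05 with separated pools. Places left open are filled at an unadjusted p under 0.01 with separated pools. Because no gene passed, all were filled in that way: the higher ones were Tnfrsf9, Mpo, Camp, Sphkap, Pdk1, Ngp, Mgarp, Ctsg, Mt1, Slc2a3, Adm and Ackr2. The rule also names up to 4 members of each list by smallest p, and 10 genes whatever their values, of which Epo was not analysed here and 1 other is not reported here. Of 104 named genes, 41 had several tested probe sets, and for 5 (Fdft1, Mcm3, Nefl, Ret and Steap2) these differed in sign.

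A background was set per array as the highest of 27 unspiked control probe sets (8.5, 8.2, 14.4 and 13.3), and "at least" folds compare the brighter group with the higher of that background and the dim signal. Where only 1 pool of a group was above background, the text also gives the difference, or gives it instead, with the lower signal set to background. Both were chosen after the data were seen. The bounded genes are Tnfrsf9, Ctsg, Cyp2j5, Mfsd4b1, Slc7a13, Slc22a19, Ugt2b5 and Miox.

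Alternatives fixed in advance were no filter, leaving out the lowest 60%, quantile normalization, median centring, an intensity trend or robust hyperparameters in eBayes, array weights, the replicate number as a block, each pool left out in turn, an adjusted p of 0.10, 1 probe set per gene, camera with an estimated correlation, and fry. An offset of 16 before the log was added after the data were seen. The procedure was tested on simulated data with variances drawn from the fitted prior of this comparison, in 10 runs over 27022 probe sets with 50 changed at each fold. At an adjusted p of 0.05 it recovered 0% of 2-fold, 0% of 4-fold, 1.2% of 8-fold and 10.6% of 16-fold changes, with 0.9 false calls per run. At an unadjusted p of 0.05 it found 51.2%, 92.2%, 97.8% and 99.6% of them. Camera called 20 of 20 lists of 25 genes shifted by 1 log2 unit and 0.139% of unshifted lists, on independent genes.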

Results

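The series measured RNA from kidneys of C57BL/6 mouse embryos at embryonic day 15, a stage at which nephrons are forming while the collecting system branches. Dams ate either a control diet with 220 ppm iron or an iron-deficient diet with 2 to 6 ppm iron, starting 3 weeks before gestation. Each diet was represented by 2 pools of 16 kidneys, and each pool was hybridised to 1 Affymetrix array that carries 45101 probe sets. Of these, 27022 were bright enough to be tested, and they covered 12997 gene symbols. The median signal was 42.5 in control pool 1, 31.5 in control pool 2, 40 in iron-deficient pool 1 and 34 in iron-deficient pool 2. The share of probe sets above the array's own background was 74.4% and 69.6% in the control pools and 66.2% and 63.3% in the iron-deficient pools. The number of arrays, 2 per diet, limits the precision of every value. The labels do not say whether pools of a diet came from separate litters. Limma p-values of single probe sets therefore measure only the spread between these pools, which may be technical. Camera p-values with the preset correlation of 0.01 rest mainly on the spread among genes. The estimated correlation was 0.103 for the hypoxia list and 0.578 for the proximal tubule list, so the preset value understates it there.

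The comparison of diets asked which transcripts differ between kidneys of embryos carried by iron-deficient and by control dams. Signals of hypoxia response genes were higher in the iron-deficient pools, and signals of genes of the proximal tubule, the nephron segment that reabsorbs most of the filtrate, were lower. Adm, which encodes the vasodilator peptide adrenomedullin, averaged 482 in the control pools and 2661 in the iron-deficient pools (log2 difference 2.42 ± 0.42, SE). Fbp1, a gluconeogenic enzyme of the proximal tubule, averaged 827 in the control pools and 35.8 in the iron-deficient pools (log2 difference -5.09 ± 0.87, SE). Its signal was above background in 1 of 2 iron-deficient pools, and with the other signal set to background the difference was -4.79. Embryonic globins were also higher, and Tfrc, the transferrin receptor, differed by 0.51 ± 0.31 on the log2 scale. None of these genes passed the test over all probe sets.

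Of 37 gene lists tested, 8 shifted higher and 4 shifted lower by limma's camera test with a preset correlation of 0.01, at an adjusted p of 0.05. With an estimated correlation, no list passed (smallest adjusted p = 0.402), and none passed by fry (smallest adjusted p = 0.0808). No single probe set passed over all 27022 by limma, with a smallest adjusted p of 0.289. At an unadjusted p under 0.05 lay 1069, which is 3.96% of those tested. In the simulation, with variances drawn from the fitted prior, 4.95% of unchanged probe sets lay there, and the count was below that share. The standard deviation of log2 differences was 0.964 between the iron-deficient pools and 0.504 between the control pools. With arrays so unlike in spread, the simulated share cannot decide whether the count exceeds what no difference would give. With 1 probe set per gene symbol, limma called 1 gene higher and 12 lower. The gene called higher was Tnfrsf9 (adjusted p = 0.0189), and those called lower were Slc17a1, Slc22a19, Ugt2b5, Mfsd4b1, Slc22a22, Cyp2j5, Slc5a1, Hgd, Akr1c21, Mfsd4b5, Defb1 and Kl, with adjusted p from 0.0189 to 0.047. Limma used the signals themselves here, also where they lay below background, as for Tnfrsf9 in both control pools. At 1.5-fold and an unadjusted p of 0.05, 309 probe sets were higher and 760 lower, so that 28.9% of them were higher. That share was 54.8% after each array was centred on its median (581 higher, 479 lower) and 40.5% after quantile normalization (420 higher, 617 lower). These counts were 874 and 195 without control pool 1, 109 and 225 without control pool 2, 845 and 1740 without iron-deficient pool 1, and 3441 and 7008 without iron-deficient pool 2. At the adjusted threshold, 42 were higher and 33 lower without control pool 1, and 6 and 25 without control pool 2. Both iron-deficient pools lay above both control pools for 3181 probe sets and below both for 6748, together 36.7% of those tested, where chance gives 33.3%. The median tested probe set was lower in the iron-deficient pools, with a log2 difference of -0.103. Relative to it, the median of the hypoxia list was 1.25 and that of the proximal tubule list -1.74.

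The pools also differed in signals that diet does not name. Eif2s3y, a Y-linked gene, had signals of 594.5 and 600 in the control pools, 253.6 in iron-deficient pool 1 and 20.8 in iron-deficient pool 2. Xist, which is expressed from the inactive X chromosome, had signals of 927 and 168 in the control pools and 3427 and 1543 in the iron-deficient pools. The labels give the sex of every sample as female. The array of iron-deficient pool 1 stood apart, since the correlation across probe sets of its log2 signals with those of the other arrays was 0.883 to 0.913, where the control pools reached 0.978. Probe sets are not independent replicates in these correlations. Its control probe set for the 5′ part of 18S ribosomal RNA read 2144.5, against 291.9 and 289.4 in the control pools and 243 in iron-deficient pool 2.

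**Figure D1:**
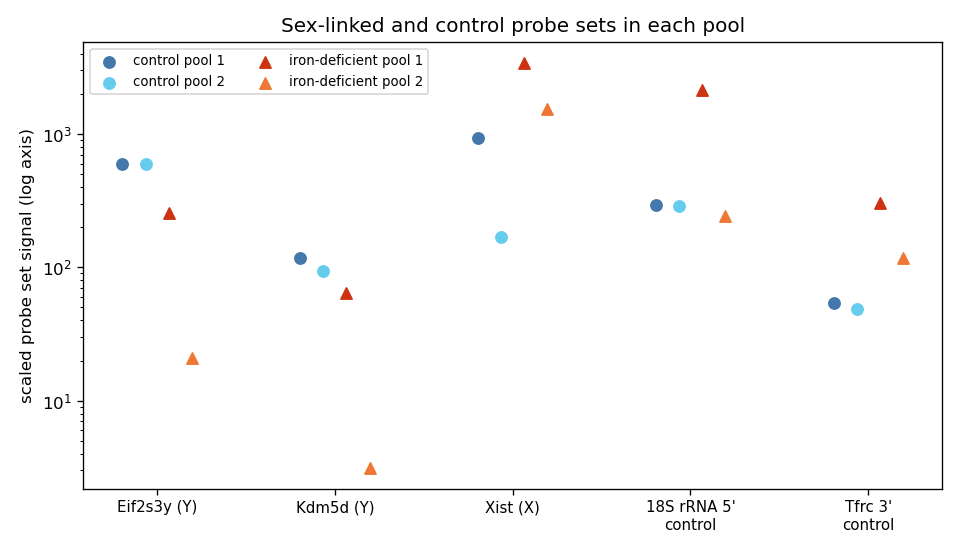
Signal of Y-linked, X-linked and control probe sets on a log axis, with 1 point per pool and circles for control and triangles for iron-deficient pools. Eif2s3y lies lower in both iron-deficient pools, at 253.6 and 20.8, and the 18S control probe set stands out at 2144.5 in iron-deficient pool 1.

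Genes that answer to low oxygen shifted higher. Of 30 tested members, 27 were higher in both iron-deficient pools than in both control pools and 1 was lower in both, with a median log2 difference of 1.15. Adjusted over the list alone, 14 members were higher and 1, the carbonic anhydrase Car12, was lower, while none passed over all genes tested. Hk2, the hexokinase that starts glycolysis, averaged 604 in control and 1825 in iron-deficient pools (1.60 ± 0.31, SE). Pfkfb3, an activator of glycolytic flux, differed by 1.59 ± 0.33, and Pdk1, a kinase that restrains entry of pyruvate into the citric acid cycle, by 1.43 ± 0.33. The glucose transporter Slc2a1 averaged 2124 and 5385 (1.34 ± 0.34), and the angiogenic factor Vegfa averaged 188 and 464.4 (1.31 ± 0.32). A dimmer Vegfa probe set, whose pools overlapped between diets, differed by 0.64 ± 0.42. The related glucose transporter Slc2a3 was among the largest differences by the naming rule, at 2.63 ± 0.36, and did not pass over all genes. The list shifted higher with adjusted p = 5.69e-25 by camera, and adjusted p = 0.402 with an estimated correlation. Its median was 1.20 without iron-deficient pool 1, whose array stood apart, and 0.87 without iron-deficient pool 2, whose Eif2s3y signal was 3.48% of the control mean. That signal was 42.5% in iron-deficient pool 1, so leaving out pool 2 does not remove the difference in sex-linked signals.

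**Figure D2:**
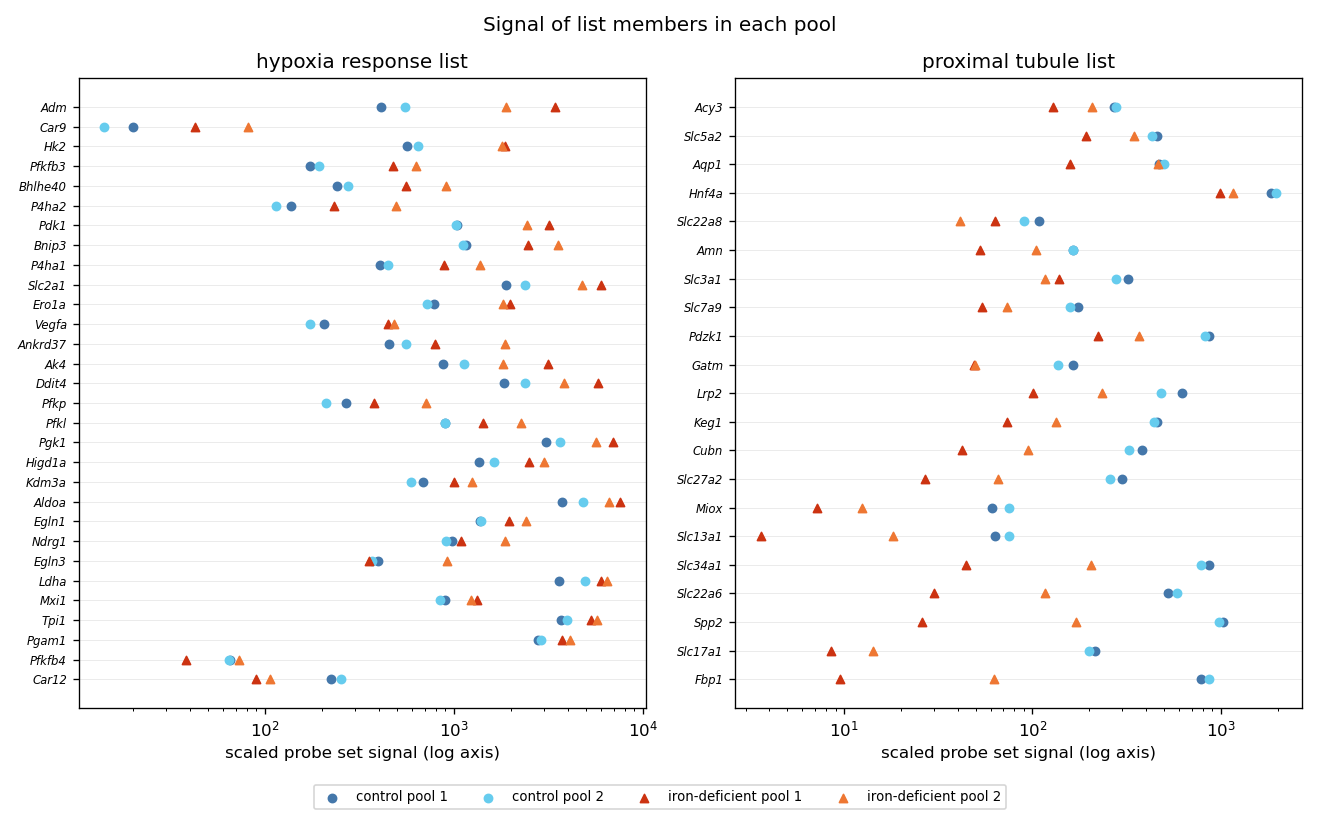
Signal of each tested member of the hypoxia response and proximal tubule lists on log axes, with 1 point per pool. Of 30 hypoxia members, 27 lie higher in both iron-deficient pools than in both control pools, and all 21 proximal tubule members lie lower.

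Markers of the proximal tubule shifted lower, with a median log2 difference of -1.84. All 21 tested members were lower in both iron-deficient pools than in both control pools. When adjusted over the list alone 15 passed, against 0 over all 27022 probe sets, while Slc17a1 passed with 1 probe set per gene (limma adjusted p = 0.0189). Slc17a1, a sodium-dependent phosphate transporter, had signals of 215.4 and 199.5 in control pools and 8.5 and 14.3 in iron-deficient pools (-4.23 ± 0.38, SE), of which only the 14.3 was above background, and the difference was -3.85 with the other signal set to background. Miox, which breaks down inositol, was at least 4.89-fold lower, because its signal was not above background in either iron-deficient pool. Slc27a2, a fatty acid transport protein, differed by -2.72 ± 0.50. The largest negative differences by the naming rule, none of which passed over all 27022 probe sets, included several bounds. With 1 probe set per gene, Slc17a1, Slc22a19, Ugt2b5, Cyp2j5, Mfsd4b1, Defb1 and Kl passed, as given above. Their tests used the signals and not the bounds, and for Slc22a19, Ugt2b5, Cyp2j5 and Mfsd4b1 both iron-deficient signals lay below background. Slc22a19, an organic anion transporter, was at least 13.8-fold lower, Ugt2b5, a glucuronosyltransferase, at least 9.24-fold lower, Cyp2j5, a cytochrome P450, at least 8.54-fold lower, Slc7a13 at least 8.31-fold lower and Mfsd4b1 at least 8.20-fold lower. Cyp2d26, Slc5a8 and Kl, which encodes the FGF23 co-receptor klotho, were above background in 1 of 2 iron-deficient pools. With the other signal set to background they differed by -4.05, -3.94 and -3.38 on the log2 scale. The same held for the dimmer probe set of Defb1 (-4.28), while its brighter probe set, above background in all pools, differed by -4.21 ± 0.53. Spp2, above background in all pools, differed by -3.92. The list shifted with adjusted p = 2.40e-23 by camera and adjusted p = 0.458 with an estimated correlation. Its median was -1.61 without iron-deficient pool 1 and -2.45 without iron-deficient pool 2. The 18S control signal was high in pool 1 alone, and the Y-linked signal was lowest in pool 2, where the shift was smaller.

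Markers of the loop of Henle and distal tubule shifted lower as well. Of 10 tested members, 8 were lower in both iron-deficient pools, 4 passed when adjusted over the list alone and none passed over all genes, with a median of -0.92. Umod, the urinary protein uromodulin, averaged 107.5 in control and 22.1 in iron-deficient pools (-2.37 ± 0.43, SE). Cldn16, a tight junction protein, differed by -1.91 ± 0.42, Slc12a1, the furosemide-sensitive salt transporter, by -1.72 ± 0.40, and the potassium channel Kcnj1 by -2.59 ± 0.64. The adjusted p was 8.89e-05 by camera, adjusted p = 0.562 with an estimated correlation, and 0.0942 without iron-deficient pool 2 (1.32e-06 to 0.0942 over the alternatives). With the lowest 60% of probe sets left out, the median was -1.72. In the urothelium list, 5 of 7 members were lower in both iron-deficient pools and 3 passed when adjusted over the list alone, with none over all genes and a median of -0.73. Upk3a, a uroplakin of the urothelial surface, averaged 270.9 and 60.6 (-2.20 ± 0.37), and Upk2 and Upk1b differed by -1.29 and -1.03. That list had adjusted p = 0.00488 by camera and adjusted p = 0.458 with an estimated correlation, and without iron-deficient pool 2 its median was -1.11 with adjusted p = 0.56 (4.85e-05 to 0.56 over the alternatives). Iron-deficient pool 1, whose array stood apart, had the lower medians of both lists, at -1.17 and -1.11.

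Progenitor and glomerular lists did not pass the test. The nephron progenitor list of 13 members had a median of -0.25 (adjusted p = 0.976), and Six2, which keeps progenitors undifferentiated, differed by 0.44 ± 0.34. The early nephron list had adjusted p = 0.41 and the podocyte list adjusted p = 0.979. Wnt4, which drives the first epithelial vesicles, differed by -0.08 ± 0.38, a sign that turned after quantile normalization and median centring. Jag1, a Notch ligand, differed by 0.77 ± 0.40 and the slit diaphragm gene Nphs1 by -0.98 ± 0.43 (0.35 and -0.49 without iron-deficient pool 1). The ureteric bud and collecting duct list had a median of -0.29 (adjusted p = 0.108), and it passed without iron-deficient pool 1, at adjusted p = 0.0266 (0.0266 to 0.695 over the alternatives). Avpr2, the vasopressin receptor of the collecting duct, averaged 80.4 and 32 (-1.33 ± 0.32). Stroma (adjusted p = 0.287), smooth muscle (0.259) and endothelium (0.745) did not pass, although Flt1, a VEGF receptor, averaged 295.6 and 1175 (1.92 ± 0.42). Other Flt1 probe sets differed by 0.44 ± 0.33, 1.20 ± 0.39 and 1.34 ± 0.33. The adrenal list had adjusted p = 0.893, and 0.0425 with a median of -0.43 without iron-deficient pool 1 (0.0425 to 0.98 over the alternatives). The renin-angiotensin list of 4 tested members, the gonad list of 1, the mesothelium list of 3 and the Y-linked list of 2 held too few for the test, with medians of -0.50, -0.24, -0.32 and -2.97.

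Embryonic globin and red cell genes shifted higher. Of 15 tested erythroid members, 8 were higher in both iron-deficient pools and 2 lower, 7 passed as higher when adjusted over the list alone and none over all genes, with a median of 0.82. The members that passed included the embryonic globins Hbb-bh1 (40.7 and 221.9 on average, 2.44 ± 0.34) and Hba-x (1.96 ± 0.36), Hemgn, a red cell nuclear protein (2.49 ± 0.32), and the blood group gene Ermap (1.97 ± 0.38). Alas2, the first enzyme of haem synthesis in red cells, went the other way, with averages of 500 and 220.6 (-1.30 ± 0.47, or -0.71 without iron-deficient pool 1), and did not pass. Adult globin probe sets differed less, at 0.07 for Hba-a2 and 0.01 for Hbb-b2, but these genes have near-identical copies and their values are uncertain. The probe set of Hba-a1 was too dim to be tested. The list had adjusted p = 3.17e-09 by camera and adjusted p = 0.402 with an estimated correlation. Its median was 0.49 without iron-deficient pool 2, whose Eif2s3y signal was 3.48% of the control mean, against 42.5% in iron-deficient pool 1. In iron-deficient pools 1 and 2 the erythroid medians were 0.49 and 1.08 and those of the liver list -1.12 and 1.25, and the granulocyte genes Mpo and S100a8 were higher in both of these pools than in both control pools.

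Iron-handling genes did not shift together, and a list that mixes uptake, storage and export could hold opposite changes that cancel in its median. The 21 tested members of the uptake, storage and export list had a median of -0.01 (adjusted p = 0.871), a sign that turned relative to the median probe set (0.09), with 3 members higher and 5 lower in both iron-deficient pools. In iron-deficient pool 2 by itself, 9 were higher and 8 lower than both control pools, and in pool 1 these counts were 6 and 9. Tfrc averaged 1887 in control and 2691 in iron-deficient pools, and its dimmer probe sets differed by 1.33 ± 0.58 and 0.55 ± 0.40, or by 0.55 and 0.14 without iron-deficient pool 1. Its control probe sets, which were not tested, read 54 and 48.4 in control and 303.1 and 117.1 in iron-deficient pools at the 3′ part. In the middle they read 33.4 and 34 against 84.9 and 83.8, and at the 5′ part 26.8 and 20.5 against 34.9 and 31.2. Steap2, a metalloreductase, differed by -0.93 ± 0.32, while another of its probe sets had a difference of 0.003. Haem synthesis and breakdown (adjusted p = 0.552), with Uros at -1.07 ± 0.46, and iron-sulfur cluster assembly (0.439), with Nubp2 at -0.95 ± 0.46, did not pass, and the 2 genes differed by -0.51 and -0.39 without iron-deficient pool 1. Iron-dependent dioxygenases shifted higher, with a median of 0.43. Of 28 members, 12 were higher and 1 lower in both iron-deficient pools, and none passed when adjusted over the list alone or over all genes. Against both control pools, 21 were higher and 3 lower in iron-deficient pool 2, and 16 higher and 10 lower in pool 1. The collagen hydroxylases P4ha1, P4ha2 and Plod2 and the histone demethylase Kdm3a differed by 1.38 ± 0.37, 1.44 ± 0.46, 1.21 ± 0.34 and 0.82 ± 0.33. Camera gave an adjusted p of 5.87e-06, and adjusted p = 0.402 with an estimated correlation. In this list 5 members are also in the hypoxia list, and the other 23 had a median of 0.23, with camera p = 0.000475 and p = 0.061 with an estimated correlation, a test chosen after the data were seen.

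Imprinted growth genes shifted higher, with 11 of 12 members higher in both iron-deficient pools and none lower, none passing when adjusted over the list alone, and a median of 0.55. Meg3, a maternally expressed noncoding RNA, averaged 326 and 1138 (1.84 ± 0.44). Zim1 differed by 1.16 ± 0.34, Dlk1, a Notch pathway ligand, by 1.11 ± 0.42 (0.66 without iron-deficient pool 2) and Igf2r, the receptor that clears IGF2, by 0.80 ± 0.42 (0.34 without iron-deficient pool 1). By camera the adjusted p was 1.73e-06 and adjusted p = 0.402 with an estimated correlation. The median was 0.30 without iron-deficient pool 1, whose array stood apart, and 0.16 after quantile normalization. Gdnf-Ret and FGF signalling had 5 of 21 members higher and 1 lower in both pools, with none passing when adjusted over the list alone, a median of 0.18 and adjusted p = 0.00801 by camera, and adjusted p = 0.458 with an estimated correlation. Its call was lost without iron-deficient pool 1 (adjusted p = 0.458, median 0.11) and without the filter on dim probe sets (0.0532), with a range of 0.00159 to 0.458 over the alternatives. Its median was 0.29 after quantile normalization, 0.37 after median centring and 0.35 without iron-deficient pool 2. In iron-deficient pool 2, 11 members were higher and 6 lower than both control pools, with 12 higher and 8 lower in pool 1. Sox9, a transcription factor of the branching tips, had signals of 342.1 and 291.7 in control pools, 3529 in iron-deficient pool 1 and 409.1 in iron-deficient pool 2. Sox8 differed by 1.47 ± 0.79, the ERK phosphatase Dusp6 by 0.76 ± 0.42 and Ret, the GDNF receptor, by 0.18 ± 0.44, and these were 0.38, 0.29 and -0.33 without iron-deficient pool 1. The extracellular matrix list had 13 of 28 members higher and 3 lower, with none passing when adjusted over the list alone, a median of 0.27 and adjusted p = 0.00536 by camera, and adjusted p = 0.656 with an estimated correlation. Its call was lost without control pool 1 (0.0593), control pool 2 (0.0631) or iron-deficient pool 2 (0.219, median 0.05), with a range of 0.000216 to 0.219. In iron-deficient pool 2, 21 members were higher and 4 lower than both control pools, with 14 higher and 10 lower in pool 1, and the list's median was 0.10 after quantile normalization and 0.47 after median centring. Col1a1, a fibrillar collagen, differed by 0.77 ± 0.40 (0.36 without iron-deficient pool 1) and Fbn2 by 0.59 ± 0.31.

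The camera calls of the leukocyte, interferon and muscle lists were lost when certain single pools were left out. Macrophage and other leukocyte markers shifted lower, with 11 of 16 members lower in both iron-deficient pools, none passing when adjusted over the list alone, and a median of -0.54. Lyz2, a lysozyme, averaged 728 and 329.6 (-1.17 ± 0.38), and the complement gene C1qa differed by -0.84 ± 0.45 (-0.33 without iron-deficient pool 1). Camera gave an adjusted p of 0.00488, and adjusted p = 0.656 with an estimated correlation. It was 0.137 without control pool 2 and 0.129 without iron-deficient pool 2, with a range of 0.0023 to 0.137 over the alternatives, and the median was -0.26 without iron-deficient pool 1, -0.35 after median centring and -0.32 with the lowest 60% of probe sets left out. Interferon response genes shifted higher, with a median of 0.25, 3 of 13 members higher and 2 lower in both pools, and none passing when adjusted over the list alone. Usp18, a negative regulator of interferon signalling, averaged 36.5 and 94.3 (1.37 ± 0.31), and Ifit3 differed by 1.04 ± 0.31. The adjusted p was 0.00625 by camera, and adjusted p = 0.758 with an estimated correlation. It was 0.0676 without control pool 1, 0.459 without iron-deficient pool 2, where the median turned to -0.14, and 0.504 with the lowest 60% of probe sets left out, with a range of 0.000421 to 0.504. Without iron-deficient pool 1 the median was 0.66, with 10 members higher and 2 lower than both control pools in pool 2, against 4 and 8 in pool 1, and it was 0.45 after median centring. Skeletal muscle markers shifted higher, with a median of 1.67 and 2 of 6 members higher in both pools, both of which passed when adjusted over the list alone. They were the muscle transcription factors Myog (2.37 ± 0.48) and Myod1 (1.64 ± 0.32). The muscle actin Acta1 had signals of 37.4 and 17.4 in control pools, 35.2 in iron-deficient pool 1 and 264.7 in iron-deficient pool 2. The adjusted p was 5.04e-05 by camera, adjusted p = 0.562 with an estimated correlation, and 0.322 without iron-deficient pool 2, where the median was 0.20 (9.21e-10 to 0.322 over the alternatives). In iron-deficient pool 2 by itself, all 6 members were higher than both control pools, with 2 higher and 2 lower in pool 1.

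**Figure D3:**
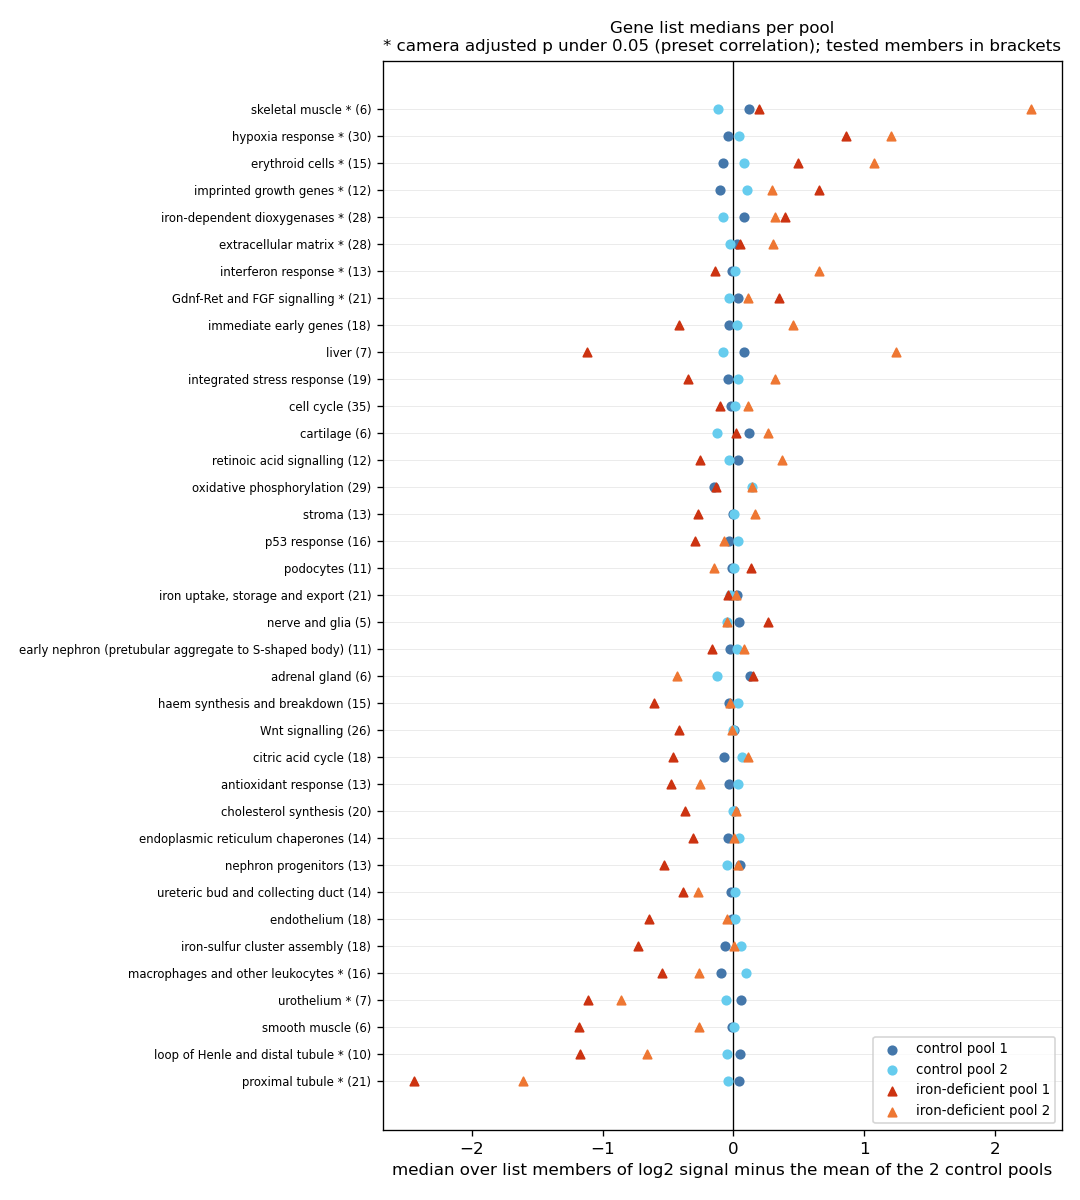
Median over the members of each list of log2 signal minus the mean of the control pools, with 1 point per pool, circles for control and triangles for iron-deficient pools. An asterisk marks an adjusted p under 0.05 by camera with a preset correlation, and the numbers in brackets are tested members. The hypoxia list lies at 0.87 and 1.20 and the proximal tubule list at -2.45 and -1.61 in iron-deficient pools 1 and 2.

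Energy, stress and proliferation lists did not pass. The adjusted p was 0.376 for oxidative phosphorylation, 0.687 for the citric acid cycle, 0.893 for cholesterol synthesis, 0.259 for the cell cycle, 0.893 for the p53 response, 0.893 for endoplasmic reticulum chaperones and 0.998 for Wnt signalling. Mcm3, a replication licensing factor, differed by 0.57 ± 0.33 and Idh3a, a citric acid cycle enzyme, by -0.80 ± 0.32. The integrated stress response had adjusted p = 0.259, the antioxidant response 0.511, the immediate early genes 0.187 and retinoic acid signalling 0.15. Without iron-deficient pool 1 these lists passed, at 7.97e-05, 0.0498, 0.000203 and 0.00279, with medians of 0.32, -0.26, 0.46 and 0.37. Over the alternatives the adjusted p reached 0.695, 0.997, 0.982 and 0.873. Immediate early genes also passed with the lowest 60% of probe sets left out (0.0155). Trib3, a stress-induced pseudokinase, differed by 1.76 ± 0.57 (0.98 without iron-deficient pool 2), Gclm, a subunit of the glutathione-forming ligase, by -1.14 ± 0.32, and Cyp26b1, which degrades retinoic acid, by 1.89 ± 0.60 (1.05 without iron-deficient pool 1). Nerve and glia (adjusted p = 0.259) and cartilage (0.511) did not pass. The liver list did not pass with all pools (0.71). Median, mean and test differed in sign for iron uptake, oxidative phosphorylation, cholesterol synthesis, cell cycle, nephron progenitors, early nephron, nerve and glia, liver and cartilage.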

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

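Control probe sets, which no comparison uses, read above both control pools on the array of iron-deficient pool 1. Those for 18S ribosomal RNA read 595.7 at the 3′ part, 2144.5 at the 5′ part and 5580 in the middle. In the control pools these read 171.8 and 140.5, 291.9 and 289.4, and 2702.5 and 2868.9. Spike-in controls averaged 1.82 times the mean of the control pools. Control probe sets of the transferrin receptor read 303.1 at the 3′ part, against 54 and 48.4 in the control pools, and 84.9 in the middle, against 33.4 and 34. In iron-deficient pool 2 the transferrin receptor controls read 117.1 and 83.8. Unlike the 18S controls, they were thus higher in both iron-deficient pools than in both control pools. No explanation of these values was tested.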

How the results depend on the processing

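Offsets, setting signals to background and leaving out iron-deficient pool 1 for counts of members were chosen after the data were seen. Of the shifts of single lists under the alternatives, 467 kept their side of the threshold (the median turned sign in 53 of these, none of which passed), 8 passed only under the alternative and 37 no longer passed, and for named genes these counts were 1243, 82 and 0, with 7 reversed. That 0 was fixed in advance, because no named gene passed in the main fit. At 1.5-fold, 942 probe sets were higher and 1097 lower with no filter, and 187 and 522 with the lowest 60% left out, where the number tested changed. After median centring 581 were higher and 479 lower, and the cause was not tested. With the replicate number as a block, 261 were higher and 218 lower at the adjusted threshold, and 1228 and 1115 at 1.5-fold. The labels pair no pools, and the numbers give only 2 pairs, with a correlation of differences of 0.357, which does not settle whether numbers pair the pools. With 1 probe set per gene, 1 gene was higher and 12 lower, with fewer tests and a variance prior fitted anew (5.35 degrees of freedom against 3.49). With an estimated correlation 0 lists were higher and 0 lower, and with fry 0 and 0. Leaving out each pool in turn gave 0 to 42 probe sets higher and 0 to 33 lower at the adjusted threshold, 109 to 3441 higher and 195 to 7008 lower at 1.5-fold, and 5 to 11 lists higher and 1 to 7 lower. A pool alone in its group is assumed there to vary like the other group. Reversed values were Cox7a2 at -0.027 after quantile normalization, Myh3, which ranged from -0.068 without iron-deficient pool 2 to 3.46 without iron-deficient pool 1, Wnt4 at 0.10 after quantile normalization, 0.12 after centring, 0.02 without control pool 2 and 0.26 without iron-deficient pool 1 (-0.42 without iron-deficient pool 2), and Ret, which ranged from -0.33 without iron-deficient pool 1 to 0.69 without iron-deficient pool 2, and the cause was not tested. Robust hyperparameters were not run for lists, since camera has no such option. Signal over background limits genes near 8.2 to 14.4. Folds are bounds where no pool of a group was above background. Where 1 pool was, differences rest partly on signals below it. The dimmer probe set of Defb1 was at -5.63, or -4.28 with that signal set to background.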

Other observations

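Granulocyte genes were among the largest positive differences by the naming rule, none of which passed over all 27022 probe sets. Of the tests here, those of normalization, of the array of iron-deficient pool 1, of sex, of handling and of blood were chosen after the result was seen. Mpo, the myeloperoxidase of neutrophil granules, had signals of 13.1 and 11.6 in control pools and 388.4 and 119.7 in iron-deficient pools (4.13 ± 0.60, SE). Camp and Ngp, which encode granule proteins, were above background in 1 of 2 control pools, and with the other signal set to background they differed by 3.64 and 2.54, while Ctsg, a granule protease, was at least 6.01-fold higher. A hypothesis is that the iron-deficient pools held more granulocyte precursors. Of a list of 19 further granulocyte genes, written before it was tested, 8 were tested, and their median was 0.783 (camera p = 0.000888, and p = 0.0751 with an estimated correlation), which is consistent with it. Of these 8, 4 were higher in both iron-deficient pools than in both control pools (S100a8 by 2.11, S100a9 by 1.95, Prtn3 by 1.30 and Ms4a3 by 1.27), and 3, Lyz2, Lcn2 and Hp, were lower in both. Lyz2 is also in the leukocyte list, and Lcn2, which kidney tubules also express, in the iron list. Tnfrsf9, a receptor of activated lymphocytes, was at least 27.3-fold higher, and it passed with 1 probe set per gene (limma adjusted p = 0.0189). That test used its control signals of 3 and 1, which lay below the backgrounds of 8.5 and 8.2, and not the bound.

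Liver genes differed between the iron-deficient pools. The median of the 7 tested liver members was -1.12 in pool 1 and 1.25 in pool 2, and the list passed without pool 1 (adjusted p = 1.48e-06, against up to 0.983 over the alternatives). Alb, serum albumin, had signals of 45.3 and 31.4 in control pools, 17.3 in iron-deficient pool 1 and 372.6 in pool 2. The muscle list had medians of 0.20 and 2.28 in the same pools. Mgarp, a mitochondrial protein, and the chemokine scavenger Ackr2 differed by 3.03 ± 0.39 and 2.52 ± 0.42, and Mt1, a metallothionein above background in 1 of 2 control pools, by 2.73 with the other signal set to background, where its brighter probe set gave 0.97 ± 0.32.

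The lower proximal tubule list was set against 3 technical explanations. After quantile normalization its median was -1.72, and without iron-deficient pool 1 it was -1.61, so neither normalization nor that array alone accounts for it. The share of male embryos stays open: 19 of 21 members were lower in iron-deficient pool 1 than in pool 2, although pool 1 had the higher Y-linked signal, but that array stood apart in other ways. Xist was also higher in pool 1 (3427 against 1543), so X-linked and Y-linked signals do not order these pools alike. The effect of diet on tubule maturation also stays open, as untested.

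For the higher hypoxia list, a stretch of bright probe sets on the iron-deficient arrays was tested. After quantile normalization its median of 1.02 lay at percentile 100 of 10000 lists matched on mean signal, of which 95% had medians from -0.186 to 0.0646, which argues against that explanation. Handling before RNA extraction could raise stress genes. Immediate early genes had adjusted p = 0.187 by camera with all pools. Their median was -0.41 in iron-deficient pool 1 and 0.46 in pool 2, where the hypoxia medians were 0.87 and 1.20. The hypoxia shift thus came without an immediate early rise in pool 1, whose array stood apart, and with such a rise in pool 2. Handling and diet cannot be told apart here. An effect of the diet stays open, as untested.

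The higher embryonic globins were set against more blood of the same kind, which would raise adult globins alike. Embryonic globins differed by 2.01 log2 units, and by at least 1.58 between any 2 pools of the 2 diets. The 6 adult probe sets differed by 0.00301 on average, with a within-group range of that mean of up to 0.321, and by -0.549 to 0.315 singly. Only 2 of them would have stayed below the highest signal of both iron-deficient arrays after such a rise, so the average cannot decide. Of these 2, 1 read 1538.4 and 1750.6 in control and 751.6 and 1672.8 in iron-deficient pools. The other read 2221.1 and 2503.3 in control and 3086.7 and 1984.7 in iron-deficient pools. Neither rose by 1.58 log2 units in either pool. However, the highest signal of an array need not be the limit of a single probe set. Probe sets of the same genes also disagreed in pool 1. Another for Hba-a1 and Hba-a2 read 3473.1 and 4548.2 in control and 5286 and 4219.1 in iron-deficient pools. These 2 probe sets therefore cannot decide either, and more blood of the same kind stays open. An earlier bound, a difference of embryonic minus adult globin above 3 times its within-group range of 0.833, was not met. A change in the kind of blood stays open, as untested. A less advanced stage would bear on globins and tubule genes together. The early-embryo genes of the Lin28-let-7 group had a median of -0.126, with 4 of 8 positive. A median at or below 0 had been set beforehand as counting against this explanation, but members went both ways and the median lay within their spread, so a delay cannot be told apart from its absence. That allowance for spread was added after the value was seen.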
